A study of Bacillus subtilis with 3 samples.

How the data were processed

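The series compared transcripts of Bacillus subtilis 3610 cells labelled remA+ and remA-, all of them also labelled epsH- and sinR-, on 3 two-channel Agilent arrays, 1 per biological replicate. Per the labels' protocols, cultures in MSgg reached an optical density of 1.0 to 1.1 before growth was stopped with cold methanol. The upper bounds in the sample descriptions were 1.1, 1.2 and 1.3 for replicates 1, 2 and 3. RNA was taken with hot phenol, treated with DNase, cleaned on a column and coupled to Cy3 or Cy5 through amino allyl nucleotides. Each array paired RNA labelled remA- with RNA labelled remA+ of the same replicate, so the replicate number pairs the samples by design. Per the labels, the RNA labelled remA+ was in Cy5 on replicates 1 and 3 and in Cy3 on replicate 2.

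Each scanner file held the intensity of every spot as the authors deposited it, from Agilent Feature Extraction 10.7.3.1 per the file headers; the submitters' processing notes name version 8.5.1.1. The median signal and median background of each channel were used as intensity on a linear scale. The scanner's own log10 ratio of red over green, per the file headers, and its other columns, such as outlier flags and calls of signal well above background, were used for filters and comparisons. The authors also deposited a table of log2 ratios per replicate with a median fold, and a matrix of log2 values. No header or label states the scale, centring or direction of that matrix. Set against the scanner's ratios, both held log2 ratios, with matrix column medians of -0.02, 0.07 and -0.05. The authors' column for replicate 2 correlated with scanner replicate 3 (r = 0.99) and the column for replicate 3 with scanner replicate 2 (r = -0.97 in red over green). In that table all columns ran as remA+ over remA-, whereas its header gives the column of replicate 2 as remA- over remA+. The matrix held the same columns, with those of replicates 1 and 3 as remA- over remA+ and that of replicate 2 the other way (r = -0.99 with scanner replicate 3 once signed to remA- over remA+). For the counts from either, columns were turned to remA- over remA+ in the direction found by this comparison. How the columns were centred stays unknown. No column of per-sample values was left out, and no header or label states a genome build.

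In the present work, signals were corrected with normexp (offset 50) and normalized within each array by loess in limma 3.58.1 under R 4.3.3, with control spots at weight 0. Mean signals had been chosen before the data were examined, but the files hold median signals, which were used in their place. Spots with a non-uniformity or population outlier flag in either channel were left out, and no spot was saturated. The 3 probes of a feature were averaged. A feature was kept where at least 1 probe was well above background in at least 1 channel on at least 2 arrays, which left 4724 of 4956. Another 13 had values on fewer than 2 arrays, so 4711 were tested, 735 of them on 2 arrays. Ratios were signed as remA- over remA+ from the dye labels, and each feature's mean was tested against 0 with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all features. A gene on 3 arrays had 4.33 degrees of freedom. The labels call the replicates biological. Replicate 1 was on slide 1 and scan 1, and replicates 2 and 3 were on slide 2 and scan 2. Each array held both groups, so a shift of a whole slide cancels in the ratio. Fold changes include the offset of 50, which lowers the ratios of dim features.

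Of 4173 numbered genes on the arrays, 4170 were named through the locus tags of a reference annotation of strain 168 (ASM904v1), used for names and neighbours only. Other features kept the names in the files. The gene lists were fixed before the data were examined. They covered the remA neighbours, the eps, tapA and opuA operons, biofilm regulators, other osmoprotectant genes, flagella and chemotaxis, sigma D motility, autolysins, competence, early sporulation, general stress, ribosomal proteins, surfactin, bacillaene, plipastatin, killing factors, iron uptake, nitrogen limitation, polyglutamate, secreted enzymes and the PBSX prophage. For 2 entries, whose first name the reference gives to another gene, another of their listed names was used. List members without a tested feature were left out. Lists were tested with camera on the fit's moderated statistics (cameraPR, preset correlation 0.01), because camera itself takes no missing values, and adjusted over the lists. Camera with an estimated correlation and fry were run on the ratios with outlier-marked spots kept, a complete matrix. With an estimated correlation camera takes its degrees of freedom from the 3 arrays, which leaves few. No list passed with it (lowest unadjusted p 0.040, sigma D motility), so it had little power to keep a call. Counts adjusted over the list alone used the same p-values adjusted within each list.

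Genes named in the text followed a rule fixed before the data were examined. It took remA, sinR and epsH, all measured members of the eps, tapA and opuA operons and of the remA neighbours, and the 15 largest decreases and 15 largest increases among genes past the threshold with the same sign on 3 arrays. From each other list it took the 4 members with the lowest p, and slrR, sinI, bslA and remB always. A few further list members are named where a count is small, chosen after their values were seen. The fit was tested on simulated arrays of 4711 features with 200 changed genes. At a true log2 size of 0.5, 1, 2 and 4, it called 0, 15, 43 and 50 of 50 genes each, all in the right direction, and 6 of 4496 unchanged features. The simulated eps list was called, and 0 of the 21 lists without a simulated change were. The simulated variances came from the fitted model and were equal on the 3 arrays. In the data the array weights were 4.30, 0.62 and 0.37 for replicates 1, 2 and 3, so the share of false calls may differ there. The simulated noise was also independent between genes, so the simulation does not test false calls of lists whose members vary together. In the data the estimated correlation was 0.94 for the PBSX prophage list and 0.92 for early sporulation. It was 0.95 for the tapA operon, 0.90 for the opuA operon and 0.31 for the eps operon, and highest for surfactin, at 0.996. The preset value was 0.01 for every list.

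The alternatives were other background corrections, normalizations, filters, flag and probe rules, a dye term, each replicate left out, other variance models and array weights, a fit of separate channels without the pairing, and the authors' 2 tables. After the data were seen, 3 were added: features measured on 3 arrays only, the authors' table in the direction its header gives, and outlier-marked spots kept without replicate 3. A random effect of slide could not be estimated from 3 arrays. Positions are not given, since the files name no build.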

Results

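Transcript levels were measured in Bacillus subtilis 3610, an undomesticated strain that forms biofilms, in RNA from cells labelled remA+ and remA-. The remA gene encodes a DNA-binding activator of biofilm matrix genes. Each of 3 two-channel Agilent arrays held RNA labelled remA- and RNA labelled remA+ from 1 biological replicate. All 6 RNAs came from cells also labelled epsH-, for a gene of exopolysaccharide synthesis, and sinR-, for the gene of the repressor of the matrix operons. The cells were grown in MSgg, a minimal medium that favours biofilms. RNA labelled remA+ carried Cy5 on replicates 1 and 3 and Cy3 on replicate 2. Each array carried 14868 spots for 4956 features, with 3 probes per feature, and 4711 features were tested. The number of arrays, 3, limits the precision. Between 78.9% and 95.7% of spots were well above background in each channel. Spots with outlier flags made up 6.99%, 1.45% and 27.8% of the spots on replicates 1, 2 and 3. On replicate 3 they fell mainly on bright spots, 68.8% of the spots in the brightest of 5 equal groups, so 732 features were tested on replicates 1 and 2 alone. Across features, which are not independent replicates, the log2 ratios of replicates 1 and 2 correlated with r = 0.70. The values were 0.52 for replicates 1 and 3 and 0.26 for replicates 2 and 3.

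The question was which transcripts depend on remA in cells labelled sinR-. All changes below are log2 ratios of RNA labelled remA- over RNA labelled remA+, the opposite of the direction found in the authors' deposited table. The remA transcript itself (BSU15670) was checked first. Its log2 ratio was -0.28, -0.28 and 0.17 on replicates 1, 2 and 3. The mean was -0.13 ± 0.16 (SE, n = 3; adjusted p = 0.72, limma), so no difference in remA transcript was detected between the RNAs. All 9 of 9 remA spots were well above background in the RNA labelled remA-, at a median of 302 times the local background. The labels do not describe the remA mutation, and the position of the probes relative to it was not known. The remA ratio therefore does not check the labels, and every direction below rests on the dye labels. Signal was also detected for epsH and sinR, which are labelled mutant in both strains. For epsH, 5 of 9 spots were well above background in each RNA, at up to 16.0 times the local background in the RNA labelled remA- and 19.2 times in the RNA labelled remA+ (medians 2.50 and 2.81). For sinR, 5 of 9 spots in the RNA labelled remA- and 4 of 9 in the RNA labelled remA+ were, at up to 9.05 and 8.54 times (medians 2.10 and 1.95). Neither ratio differed detectably from 0 (epsH 0.11 ± 0.13, adjusted p = 0.70; sinR 0.10 ± 0.12, adjusted p = 0.73; SE, n = 3 each), and these signals do not check the labels either, since the altered parts of both genes are not given.

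In the RNA labelled remA-, 35 features were lower and 21 were higher at an adjusted p under 0.05 (limma, n = 3 arrays). The largest decreases were in the genes of the biofilm matrix. Transcripts of epsA to epsF, for exopolysaccharide synthesis, fell 53.8-fold to 79.8-fold on replicates 1 and 2, which alone measured them. That of epsG fell 82.7-fold over 3 arrays and 51.0-fold without replicate 3. Those of tapA, sipW and tasA, for the matrix fibres and their processing, fell 43.0-fold to 65.2-fold. The opuA genes, for a glycine betaine importer, fell 22.3-fold to 28.5-fold. The increases were smaller. They included hag, the flagellin gene (4.66-fold), 5 chemoreceptor genes of the sigma D motility list, led by tlpA (6.01-fold), and the autolysin gene lytD (3.38-fold). Of the 56 changed features, 33 lower and 20 higher ones were numbered genes. All 56 were above background in both RNAs on at least 1 array, and the 43 measured on 3 arrays had the same sign on each. At an unadjusted p under 0.05, 345 features were lower and 327 higher. A total of 84 features, 50 lower and 34 higher, differed at least 2-fold in the same direction on each of the 3 arrays. The adjusted p-values of the 56 lay between 0.033 and 0.049, near the threshold. In limma 0 features passed without replicate 1 (101 lower and 120 higher at an unadjusted p under 0.05), 0 without replicate 2 (213 and 241), 0 with a dye term (300 and 280) and 0 after scaling the arrays to equal spread (373 and 340), whereas 40 lower and 18 higher passed without replicate 3. The fits without replicate 1 and without replicate 2 tested only 43 of the 56. The other 13, among them epsA to epsF, tasA, the opuA genes and slrR, had no unflagged spot on replicate 3. Without replicate 1 is also the value within slide 2, which held replicates 2 and 3, and slide 1 held 1 array. The split also moved with the normalization, to 64 lower and 5 higher with median centring, to 41 and 14 with Agilent's processed signals and to 49 and 16 with an offset of 0.

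**Figure D1:**
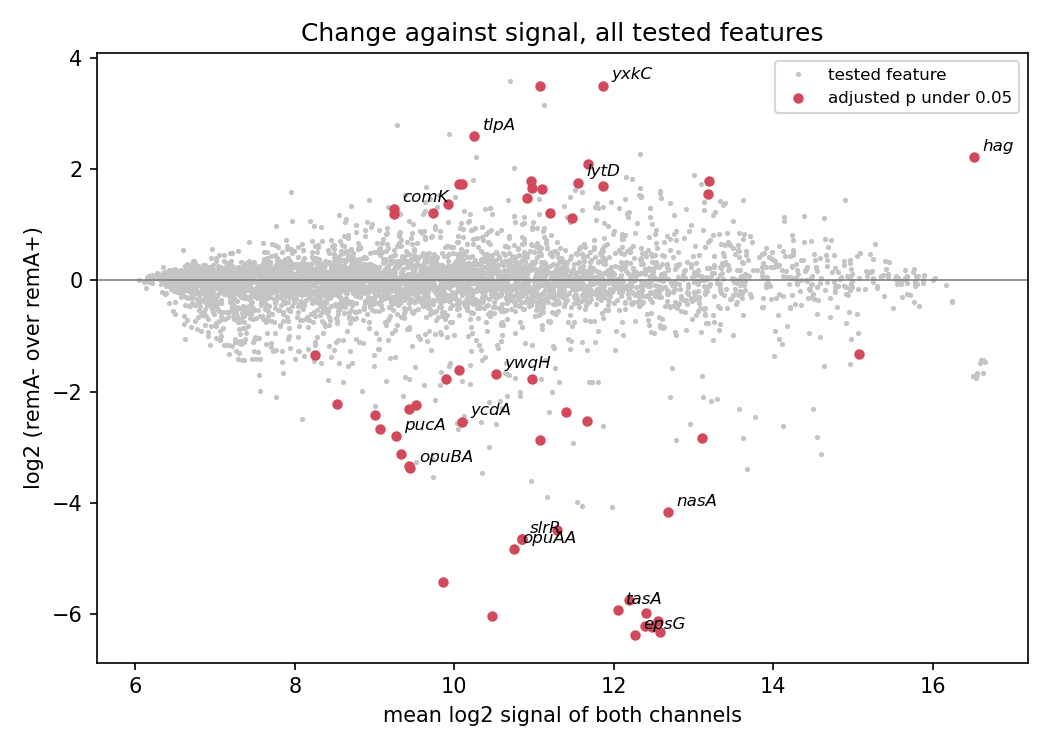
Mean log2 ratio of RNA labelled remA- over RNA labelled remA+ (vertical axis) against the mean log2 signal of both channels (horizontal axis) for the 4711 tested features. Red points mark the 35 lower and 21 higher features at an adjusted p under 0.05; the matrix genes lie lowest, with epsG, measured on 3 arrays, at -6.37 (-5.67 without replicate 3) and epsA, measured on 2, at -6.32, and yxkC lies highest among the red points, at 3.50.

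Within the eps operon, whose 15 genes build the exopolysaccharide, 8 members were lower over all genes tested, none was higher and 7 did not pass. With p adjusted over the list alone, 14 were lower. The 7 genes before epsH changed most. The mean for epsA was -6.32 ± 0.36 (SE, n = 2) and that for epsG was -6.37 ± 0.51 (SE, n = 3). On replicates 1 and 2 epsG stood at -6.01 and -5.33, the smallest change of the 7 on each, and its mean was -5.67 without replicate 3. Behind epsH the values were smaller. The mean for epsK, the member there that passed, was -1.32 ± 0.13 (SE, n = 3; adjusted p = 0.042). The values of the others, not past the threshold, ran from -0.95 at epsI and -1.05 at epsJ to -2.30 at epsN and -2.84 at epsO. The list's median was -2.84 (adjusted p = 1.6e-63, camera with preset correlation), with adjusted p = 0.32 with an estimated correlation. It was -1.08 without replicate 1 and -1.18 without replicate 2, since epsA to epsF had no unflagged spot on replicate 3.

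All 3 genes of the tapA operon fell, and all 3 passed over the list alone. The mean was -5.42 ± 0.43 (SE, n = 3) for tapA, which encodes the fibre assembly protein, and -6.03 ± 0.35 (SE, n = 3) for sipW, a signal peptidase gene. It was -5.92 ± 0.35 (SE, n = 2) for tasA, the gene of the main fibre protein. All 3 genes of the opuA operon also fell, and all 3 passed over the list alone. The means were -4.84 ± 0.29 for opuAA, -4.48 ± 0.19 for opuAB and -4.64 ± 0.30 for opuAC (SE, n = 2 each). The lists' medians were -5.92 (adjusted p = 2.7e-24) and -4.64 (adjusted p = 7.4e-35). With an estimated correlation the eps, tapA and opuA lists each had adjusted p = 0.32, so none of the 3 was called. That version has few degrees of freedom with 3 arrays and called no list at all, so it could hardly keep a call. Camera with the preset correlation on the same complete ratios gave adjusted p = 6.4e-17, 3.6e-06 and 1.2e-06 for the eps, tapA and opuA lists. Fry, which tests a list's own direction, gave 0.028 for each.

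**Figure D2:**
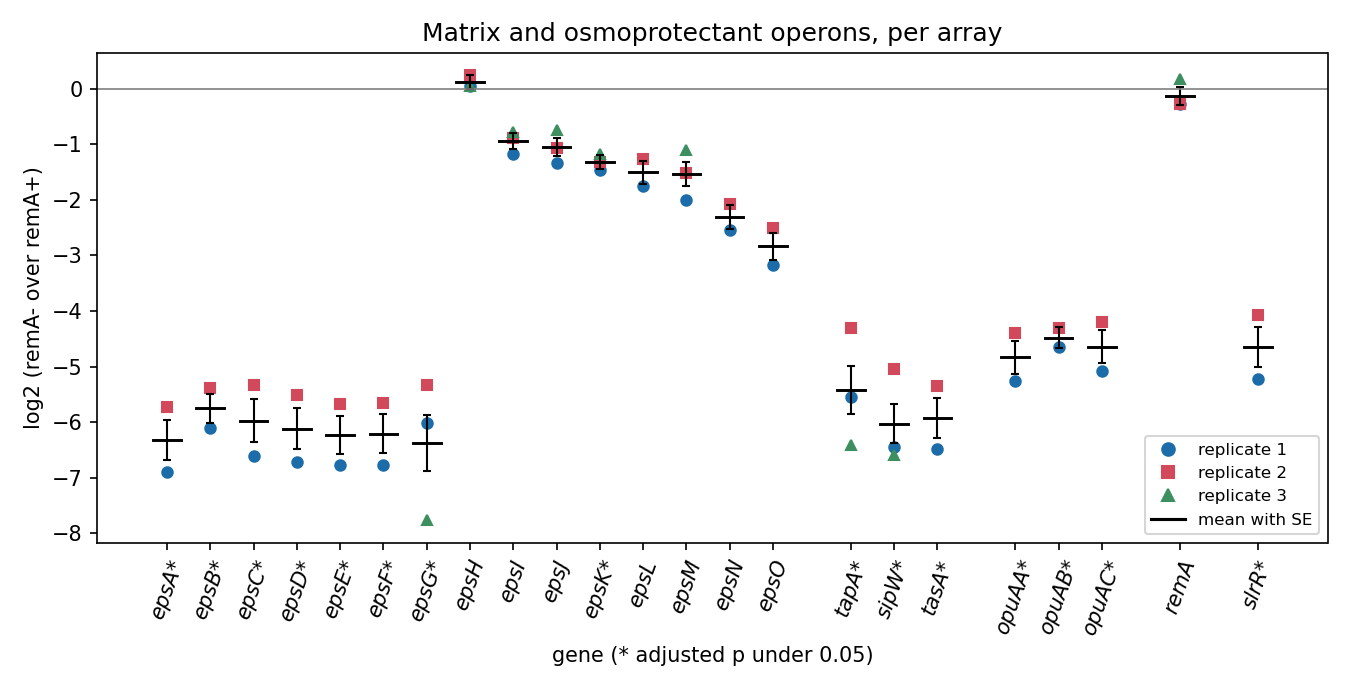
Log2 ratio of RNA labelled remA- over RNA labelled remA+ (vertical axis) for each gene of the eps, tapA and opuA operons, remA and slrR, with 1 symbol per array and the mean with its SE in black. Genes before epsH lie between -5.75 and -6.37, epsH and remA lie near 0, and the genes behind epsH lie between -0.95 and -2.84; a missing symbol is an array on which every spot of the gene had an outlier flag.

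Among the biofilm regulators and bslA, 1 of 16 genes fell over all genes tested and 3 were lower over the list alone. The gene that fell was slrR, which encodes a SinR paralog and antagonist, at -4.65 ± 0.36 (SE, n = 2; adjusted p = 0.049). The values were -2.08 for bslA, the gene of the hydrophobic biofilm coat (adjusted p = 0.16; -1.47 without replicate 3), and -1.24 for the response regulator gene degU (adjusted p = 0.14). They were -0.54 for sinI, -0.39 for degS and -0.23 for remB (adjusted p = 0.31, 0.30 and 0.71). The list was called lower (median -0.36, adjusted p = 0.0012), with adjusted p = 0.32 with an estimated correlation and 0.028 by fry, and its median was -0.19 without replicate 1. None of the 8 genes next to remA passed. Their values ran from -0.94 at yloC to -0.11 at rpoZ, with tcaB, gmk, coaBC, priA, defA and fmt between. The list of remA neighbours was not called (median -0.21, adjusted p = 0.11), but was called lower with median centring (median -0.61, adjusted p = 0.036) and with array weights (median -0.39, adjusted p = 0.039). Camera itself, run with the preset correlation and outlier-marked spots kept, also called it (adjusted p = 0.012). With an estimated correlation it was not called (adjusted p = 0.45).

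Of the other osmoprotectant genes, opuBA and opuBB fell as well. On the list of 21 measured genes outside opuA, 2 fell and 7 were lower over the list alone. These were opuBA (-3.37 ± 0.33) and opuBB (-3.34 ± 0.30; SE, n = 3 each), which passed over all genes, and opuBC (-3.21), opuCA (-3.46), opuCB (-2.99, and -2.34 without replicate 1), opuCC (-2.58) and opuCD (-2.08), which did not. The opuB and opuC operons encode transporters for choline and related compounds. The list was called lower (median -0.34, adjusted p = 1.2e-06), with a median of -0.13 without replicate 1 and without replicate 2. Both of these values leave out members without an unflagged spot on replicate 3, such as opuBC and opuCA. With outlier-marked spots kept, the list's medians were -0.29, -0.50 and -0.40 on replicates 1, 2 and 3. The list had adjusted p = 0.32 with an estimated correlation and 0.058 by fry, and the other 14 members lay between -0.57 and 0.15. The opuB and opuC genes are close paralogs, and cross-hybridisation between them was not tested.

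Of the 20 genes on the nitrogen limitation list, 1 fell over all genes tested, and 16 were lower and 1, alsT, was higher over the list alone. The nitrate transporter gene nasA fell by 4.16 ± 0.41 on the log2 scale (SE, n = 3; adjusted p = 0.041). The values of the urease genes ureA and ureC were -2.88 and -2.36 (adjusted p = 0.061 each), and that of the regulator gene tnrA was -1.10 (adjusted p = 0.099). The list was called lower (median -2.10, adjusted p = 5.5e-14), with adjusted p = 0.41 with an estimated correlation and 0.12 by fry. Its median was -2.73, -1.48 and -1.22 on replicates 1, 2 and 3, and -1.01 without replicate 1 and -1.38 without replicate 2. Members such as nasB to nasE and ureB had no unflagged spot on replicate 3, so the last 3 values cover fewer genes. With outlier-marked spots kept, the list's medians were -2.70, -1.49 and -1.88 on replicates 1, 2 and 3. The purine catabolism genes pucB (-3.12 ± 0.30), pucA (-2.80 ± 0.18), pucE (-2.67 ± 0.26) and pucI (-2.31 ± 0.20) were among the largest decreases past the threshold (SE, n = 3 each). So were ycdA, a lipoprotein gene (-2.54 ± 0.13), ykzB (-2.42 ± 0.16) and yozY (-2.24 ± 0.25). The 2 others were features without a gene name.

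Among motility genes, some of those transcribed with sigma factor D rose in the RNA labelled remA-, and none of the large flagella and chemotaxis operon passed. On the list of 21 genes transcribed with sigma factor D, 6 rose over all genes tested and all 21 were higher over the list alone. The means were 2.59 ± 0.14 for tlpA, 2.22 ± 0.14 for hag, 2.09 ± 0.15 for mcpA and 1.78 ± 0.13 for mcpB (SE, n = 3 each; adjusted p = 0.033 each). The chemoreceptor genes mcpC (1.47 ± 0.14) and tlpB (1.37 ± 0.13) passed as well. The list was called higher (median 1.32, adjusted p = 4.3e-41), with adjusted p = 0.32 with an estimated correlation and 0.028 by fry. The chemoreceptor genes tlpB, mcpA, tlpA and mcpB are adjacent paralogs, and cross-hybridisation was not tested. In the large flagella and chemotaxis operon no gene of 31 passed, over all genes or over the list alone. Its members nearest to passing were cheD (0.58), cheY (0.66), flgE (0.50) and cheC (0.46). That list was called higher (median 0.29, adjusted p = 0.0020), with adjusted p = 0.56 with an estimated correlation and 0.27 by fry. Its median was 0.23, 0.25 and 1.11 on replicates 1, 2 and 3, and 0.59 without replicate 1, 0.65 without replicate 2 and 0.23 without replicate 3. With median centring its median was 7.0e-04 and the call was lost (adjusted p = 0.65).

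Of 7 autolysin genes, which cut the cell wall, 3 rose and 4 were higher over the list alone. The means were 1.76 ± 0.12 for lytD, 1.22 ± 0.13 for lytF and 1.11 ± 0.12 for lytA (SE, n = 3 each), and the value for lytC was 1.14 (adjusted p = 0.068). The other 3 members, lytE (-0.83), cwlS (-0.17) and cwlO (-0.12), did not pass. The list was called higher (median 1.11, adjusted p = 2.8e-07), with adjusted p = 0.32 with an estimated correlation and 0.028 by fry. Of 19 competence genes, 1 rose, comK, which encodes the master regulator of competence (1.29 ± 0.14, SE, n = 3; adjusted p = 0.049). The values of nucA (0.74), nin (0.40) and comGE (0.29) did not pass, and the list was not called (median -0.01, mean 0.14, adjusted p = 0.11). It was called higher with median centring (median 0.38, adjusted p = 0.034), with the brightest probe (median 0.20, adjusted p = 0.017) and over probes above background in both channels (median 0.20, adjusted p = 0.046). The other genes that rose most were yxkC (3.50 ± 0.25), sunA, which encodes the bacteriocin sublancin (1.78 ± 0.17), ybdO (1.74 ± 0.18) and yscB (1.73 ± 0.18; SE, n = 3 each). They also included yfmS (1.69), yxaJ (1.66), yolB (1.65) and vdhT (1.54). A feature without a gene name rose by 3.49 ± 0.22 (SE, n = 3).

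No gene of the remaining lists passed over all genes tested. The PBSX prophage list was called higher (30 genes, median 0.72, adjusted p = 2.5e-07), with xkdG at 0.96, xkdH at 0.94, xlyA at 0.67 and xkdA at 0.64. It had adjusted p = 0.55 with an estimated correlation and 0.26 by fry. Replicate 3 stood apart, with medians of 0.52, 0.31 and 1.47 on replicates 1, 2 and 3, and the list was called without replicate 3 as well (median 0.46). The general stress list was called higher (31 genes, median 0.32, adjusted p = 0.0020), with gsiB at 1.30, gspA at 0.80, ctc at 0.59 and ydaG at 0.52. Its adjusted p was 0.41 with an estimated correlation and 0.082 by fry. The early sporulation list was called lower (23 genes, median -0.91, adjusted p = 7.5e-04), with adjusted p = 0.56 with an estimated correlation and 0.33 by fry. Over the list alone 1 member was lower, spo0F (-0.91 ± 0.12, SE, n = 3), beside spoIIAB at -0.91, spoIIAA at -0.79 and sigF at -0.57. The median of the sporulation list was -0.52, -0.16 and -2.73 on replicates 1, 2 and 3, and it was -1.60 without replicate 1, -1.68 without replicate 2 and -0.29 without replicate 3. The surfactin synthesis list was called higher (5 genes, median 0.77, adjusted p = 0.039), with srfAB at 0.84, comS at 0.80, srfAA at 0.77 and srfAC at 0.69. It had adjusted p = 0.86 with an estimated correlation and 0.90 by fry, and its direction turned without replicate 1 (median -0.16) and without replicate 2 (median -0.47). Both of these values are of srfAD alone, since srfAA, srfAB, srfAC and comS had no unflagged spot on replicate 3. With outlier-marked spots kept, the list's median was -1.08 on replicate 3, and the list was not called (median 0.15, adjusted p = 0.72). It was called in 13 of 22 other settings (the authors' table in its header's direction left aside), with adjusted p from 0.0070 to 0.95. The iron uptake list was called lower (34 genes, median -0.23, adjusted p = 0.025), with pbtN at -1.07, pbtO at -0.93, pbtP at -0.89 and ykuO at -0.61. It had adjusted p = 0.59 with an estimated correlation and 0.25 by fry, and it was called in 11 of the same 22 settings, with adjusted p from 0.0032 to 0.24. The call was lost without replicate 1 (adjusted p = 0.22) and without replicate 3 (adjusted p = 0.094), among others.

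The lists of ribosomal proteins (49 genes, median 0.08, adjusted p = 0.16), bacillaene synthesis (15 genes, median -0.21, adjusted p = 0.071) and plipastatin synthesis (5 genes, median 0.03, adjusted p = 0.87) were not called. Their leading members were rplQ (0.48), rpsR (0.72), pksJ (-0.75), pksD (-0.74) and ppsE (-0.14). The bacillaene list was called lower with outlier-marked spots kept (median -0.77, adjusted p = 0.022), with median centring (median -0.65, adjusted p = 0.0021) and with the authors' deposited table (median -0.84, adjusted p = 0.026). The ribosomal list was called higher without replicate 2 (median 0.17, adjusted p = 0.029) and with array weights (median 0.16, adjusted p = 0.020). The killing factors (12 genes, median -6.5e-04, mean 0.23, adjusted p = 0.36) were not called. They were called higher without replicate 1 (median 0.63, adjusted p = 0.033) and without replicate 2 (median 1.20, adjusted p = 0.010), and had a median of -0.11 without replicate 3. Both calls covered only members with unflagged spots on replicate 3, where the median was 1.62. With outlier-marked spots kept, the medians were 0.03, -0.20 and -0.26 on replicates 1, 2 and 3. In this list 1 member, the cannibalism toxin gene sdpC (spbC), was higher over the list alone (1.51 ± 0.18, SE, n = 3). The secreted enzymes (12 genes, median -0.66, adjusted p = 0.15) were not called, but were called lower without replicate 2 (median -0.89, adjusted p = 0.0093), with median centring (median -0.68, adjusted p = 0.0034) and without the pairing by array (adjusted p = 0.041). Over the list alone 2 of them were lower and 1 was higher, with the protease genes bpr at -2.56, vpr at -1.67 and epr at 1.85. For polyglutamate synthesis (4 genes, adjusted p = 0.13) the median was -0.20 while the test leaned higher. Without replicate 3 that median was 0.49 and the list was called higher (adjusted p = 0.0074). With replicate 3 kept, it was also called higher with median centring (median 0.55, adjusted p = 0.039) and with the brightest probe (median 0.45, adjusted p = 0.019). The same held with array weights (median 0.54, adjusted p = 0.043), and the list was called in 7 of 22 other settings. Its member pgdS, for a polyglutamate hydrolase, was higher over the list alone (1.45 ± 0.19, SE, n = 3), whereas capB (-1.11) and capA (-0.94) were not called, differed in sign between arrays and stood at 0.42 and 0.40 without replicate 3.

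**Figure D3:**
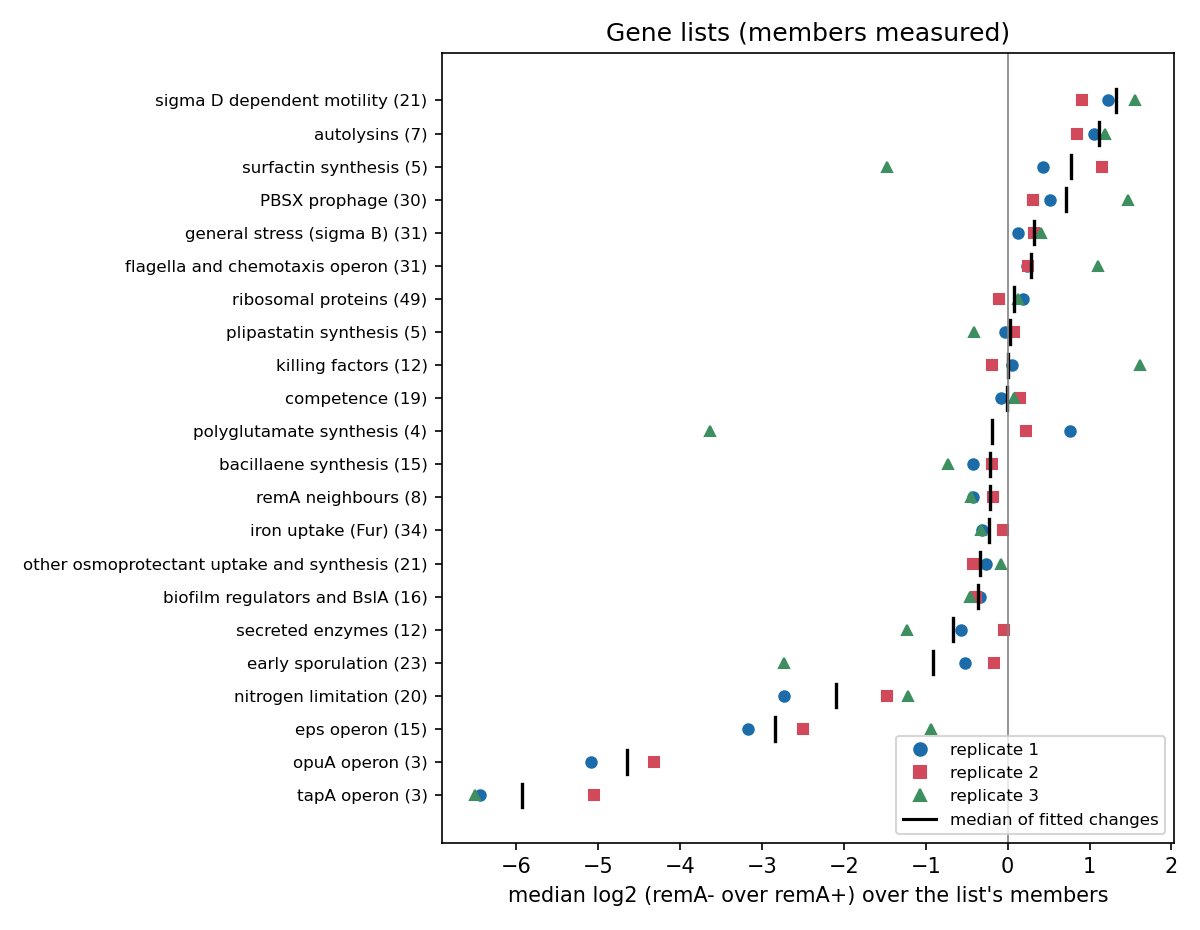
Median log2 ratio of RNA labelled remA- over RNA labelled remA+ (horizontal axis) for each gene list (rows, with the number of members measured), with 1 symbol per array over the members measured there and a black bar at the median of the fitted changes. The tapA, opuA, eps and nitrogen lists lie lowest, at -5.92, -4.64, -2.84 and -2.10, and the sigma D list lies highest at 1.32; on replicate 3 the brightest members are missing from several lists.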

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

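Chosen only after the data were seen were the tests on features measured on 3 arrays, on the authors' table in the direction of its header, and with outlier-marked spots kept without replicate 3. Of the 56 changed features, every one that an alternative measured kept its direction in it. This could hardly fail, since the features were chosen on the same arrays. Even the authors' table in the direction of its header kept 54 of 54. The counts depended on the processing, against 35 lower and 21 higher features. Median centring gave 64 and 5, probes above background in both channels on all arrays 72 and 52, and array weights 360 and 276, with weights of 4.30, 0.62 and 0.37 for replicates 1, 2 and 3. Without the filter on dim probes 9 and 9 passed. In limma, scale normalization gave 0 and 0 (lowest adjusted p 0.050; 373 and 340 at an unadjusted p under 0.05), and a dye term gave 0 and 0 (lowest 0.13; 300 and 280). Leaving out 1 replicate gave 0 to 40 lower and 0 to 18 higher, where fewer arrays were fitted. Without replicate 1 there were 0 of each (101 and 120 unadjusted), as without replicate 2 (213 and 241). Both of these fits tested 43 of the 56 features, since the others had no unflagged spot on replicate 3. Without the pairing of the 2 RNAs on an array, a fit of separate channels gave 40 and 11. After its column of replicate 2 was turned, the series matrix had 56 lower and 15 higher, and after all 3 columns were turned, 55 lower and 13 higher passed with the authors' table. Features measured on 3 arrays gave 11 and 9, and outlier-marked spots kept without replicate 3 gave 58 and 29. In the direction of its header the authors' table gave 0 and 0 in limma (57 and 55 unadjusted), with medians of -1.03, -1.78 and -1.46 for the eps, tapA and opuA lists, none called. There the flagella and chemotaxis operon (-0.20), autolysins (0.27), early sporulation (0.70) and PBSX prophage (-0.22) turned their direction by median or test, since 1 of 3 columns ran the other way. Of the lists not called, plipastatin synthesis alone was called in no alternative, and the secreted enzymes alone gained a list call without the pairing. The surfactin list ran from -0.47 to 0.80 when 1 replicate was left out, with srfAD alone measured without replicate 1 or without replicate 2. In the other settings that gave a value, tested with the preset correlation, the eps, tapA and opuA lists kept their direction and call (with an estimated correlation none was called, adjusted p = 0.32 each), and the remA transcript was not called in any. The opuA genes had no unflagged spot on replicate 3, so no value was had without replicate 1, without replicate 2 or over features measured on 3 arrays. Leaving out saturated spots moved nothing, as there were 0. A random effect of slide could not be fitted. Except where stated, the cause was not tested. Signal over background limits epsH and sinR, for which 5 of 9 spots each were well above background in the RNA labelled remA-.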

Other observations

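The search for neighbouring genes below and all other tests here were chosen only after the results were seen, except the tests of background correction on the eps operon and of outlier flags on the sporulation list. Neighbouring numbered genes, in the order of the reference annotation, were searched for stretches of at least 3 genes that differed at least 2-fold in the same direction on every array that measured them. There were 16 such stretches with 72 genes, 15 lower and 1 higher. Outside the eps, tapA, opuA, opuB and opuC operons, the largest decrease was in the nitrate genes nasE to nasA (5 genes, median -3.89, of which nasA was called), and the longest stretch ran from pxpA, for a subunit of 5-oxoprolinase, to the lipase gene lipC (7 genes, median -2.17, 0 called). In these stretches only nasA and pxpA were measured on 3 arrays, the other genes on replicates 1 and 2 alone. Another stretch ran from yueC to yukE, genes of a type VII secretion system (6 genes, values from -2.36 to -1.76). In it yukAB was called (-2.36 ± 0.17, SE, n = 2). The stretch from nfi to ywqH had a median of -1.77 over 5 genes, 3 of them called.

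The puc genes of purine catabolism formed a pair of stretches, from pucR to pucL (4 genes, median -2.36, 0 called) and from pucE to pucA (5 genes, median -2.80, 3 called). Values were also lower for yfjD to yfjB (3 genes, median -1.99, 0 called) and for the glycogen synthesis genes glgD to glgB (3 genes, median -1.13, 0 called). The glg genes were measured on replicates 1 and 2 alone. Beside slrR, the esterase gene pnbA was called lower (-2.84 ± 0.18, SE, n = 2). The 1 higher stretch held the chemoreceptor genes tlpB, mcpA, tlpA and mcpB (median 1.93, 4 called).

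The remA transcript stood at a similar level in both RNAs, at 82.4%, 82.3% and 113% of the remA+ level on replicates 1, 2 and 3. Background signal was argued against, since 9 of 9 remA spots were well above background in the RNA labelled remA-. RNA labelled remA+ mixed into the other RNA was argued against as well. A mixed share would leave every gene at least that share of its level, and the gene called lower by most kept 1.21%. Every gene called lower kept at most 40.1% of its level, under the lowest value of remA. That could hardly come out otherwise, since every called feature had changed at least 2-fold. An altered remA gene whose probed part is still transcribed may account for the pattern, but the labels do not give the altered part and the lowest remA probe stood at -0.32, so this stays open.

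Genes before epsH were lower by more than those behind it, with medians of -6.21 for epsA to epsG and -1.51 for epsI to epsO. Compression by background correction was argued against, since the gap between the medians was at least 4.78 with an offset of 0, with no background correction and with Agilent's processed signals, against 4.70 as reported. The genes behind epsH were bright, with mean log2 signals from 13.6 at epsO to 15.1 at epsK, so these settings could hardly narrow the gap. A candidate explanation is transcription that starts at the epsH mutation in both strains and does not need RemA. It stays open, since 0 RNA samples were labelled with an intact epsH.

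Early sporulation genes were lower mainly on replicate 3, with list medians of -0.52, -0.16 and -2.73 on replicates 1, 2 and 3. Outlier flags were argued against, since the median on replicate 3 was -3.41 with the marked spots kept. A dye bias of equal strength on the arrays with remA+ in Cy5 was argued against by a median difference of 2.20 between replicates 1 and 3 (SD over members 1.09). Those arrays were on different slides and scans. A bias of unequal strength was not tested and cannot be told from an effect of replicate 3 with 3 arrays. Cultures of replicate 3 harvested at another stage could account for the sporulation pattern. With the marked spots kept, 7 lists, the sporulation list among them, stood more than 0.5 apart on that array. Polyglutamate synthesis (-3.83) and bacillaene synthesis (-1.70) were lower there, also with those spots kept. The PBSX prophage and the flagella and chemotaxis operon were higher there, by 0.98 and 0.72 above the higher median of the other arrays. With 1 pair of cultures this stays open.

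For the 56 changed features, the directions of the 3 arrays allow 4 assignments. The real one gave 56 features and the highest of the others 0, so 1 assignment, the real one itself, gave that many. The 4 assignments are too few for a share under 0.05.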
